A study of Mus musculus with 6 samples.

How the data were processed

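Total RNA from livers of CYP2D6-humanized mice was extracted with Trizol, and 250 ng per liver was labelled with biotin by the GeneChip 3' IVT Express procedure, per the labels' protocols. The growth and treatment of the animals and the time of day of collection are not given in the sources used here. A difference between stages thus cannot be told apart from one in collection time or feeding, if these differed between the groups. Each liver was hybridised to 1 Affymetrix mouse array. The deposited table holds 45101 probe sets in log2 units for each of 6 arrays; RMA and Affymetrix Power Tools were used, per the submitters' processing notes, and their versions and settings are not given in the sources used here. The table does not state its scale, which was inferred from the values (arrays run from a lowest value of 2.69 to a highest of 15.05), so the log2 base is an inference. Array medians were 5.09 and 5.13 before pregnancy, 5.14 and 5.15 in pregnancy and 5.11 and 5.12 postpartum. RMA as usually run gives arrays a common distribution, which would remove a change shared by most genes, and differences near background are compressed.

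The labels give 3 groups of 2 biological replicates: pre-pregnancy, day 21 of pregnancy and day 7 postpartum. They call the replicates biological and do not say more of how the animals were chosen. No pair of arrays held identical values, and 2.43%, 2.04% and 2.46% of genes had equal values in the replicate pairs before pregnancy, in pregnancy and postpartum. For arrays, their number limits the precision.

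Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and were not named, 9160 had none here, and 64 were controls. The gene IDs of 34754 were found in the gene table used to update symbols and those of 204 were not; 0 symbols changed. No probe set was named CYP2D6 (0). No genomic coordinates are given, since no genome build is named. For each of 18194 genes the probe set with the highest mean over the 6 arrays was used, and 9012 genes had more than 1 probe set.

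Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, then eBayes) over all 6 arrays, which left 3 residual degrees of freedom beside 4.80 prior ones. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05, two-sided. SE is the moderated standard error of the log2 difference. Lists of genes were tested with limma's camera with a preset correlation of 0.01, adjusted over the 31 lists of each comparison, and again with the correlation estimated per list. With fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes, 5, 9 and 4 lists passed in pregnancy against pre-pregnancy, postpartum against pregnancy and postpartum against pre-pregnancy, of which 3, 7 and 4 were also called by camera; fry's mixed test, which asks for change in either direction, passed 29, 25 and 27. A list's median, mean and test differed in sign in lists that camera did not call, and in none (0) that it called with the preset correlation.

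Named genes were chosen by rule: genes past the threshold whose arrays did not overlap between groups and whose higher group reached the median of all genes (6.38), the 8 largest rises and 8 largest falls (5 and 5 for postpartum against pre-pregnancy), without placeholder symbols; up to 4 members of each called list, called members first; and 12 regulators and drug-metabolising enzymes whatever their values. Members that moved against their list, and members that complete a count of 6 or fewer, were named after their values were seen. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined.

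Comparisons that share arrays were set beside 100 simulations of unchanged groups. These hold no real changes, so their overlaps of calls are near 0 by design and leave out what shared arrays add where many genes are called. The alternatives were the replicate number as a block, leaving out genes under the 40th percentile of brightness (5.52), quantile normalization again, centring arrays on their medians, a trended and robust variance, the mean of all probe sets of a gene, every probe set by itself, camera on ranks, leaving out each array, fitting only the 2 groups compared, a 2-fold change and a looser threshold of 0.1. Leaving out 1 array leaves a group of 1, which is then assumed to vary like the other groups.

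The tests were checked on simulated data with 200 of 18194 genes changed, 20 times per comparison. For pregnancy against pre-pregnancy, 7.61%, 84.6% and 99.2% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 4.98% false calls. For postpartum against pregnancy these were 7.69%, 84.9% and 99.2%, with 5.46% false calls, and for postpartum against pre-pregnancy 5.67%, 84.6% and 99.2%, with 5.53%. Camera called 0.05, 0 and 0.15 of 31 unchanged lists on average. The simulated genes varied independently, so these rates do not cover lists whose members move together. Fewer genes were changed there than were called in the data (2494, 599 and 1393). The adjusted threshold depends on that share, so the recovery of small changes does not carry over to the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.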

Results

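Gene expression was measured in whole livers of CYP2D6-humanized mice, transgenic C57BL/6 animals that carry the human drug-metabolising P450 gene CYP2D6. Livers came from 3 stages: before pregnancy, day 21 of pregnancy and day 7 postpartum, with 2 biological replicates and 1 array each, 6 arrays in all. Each array carried 45101 probe sets, of which 18194 genes were tested with 1 probe set per gene. Array medians lay between 5.09 and 5.15 on the log2 scale, and replicate arrays correlated across genes at 0.997 before pregnancy, 0.994 in pregnancy and 0.996 postpartum. The number of arrays limits the precision. No probe set was named CYP2D6 (0), so the transgene itself was not analysed here; its mouse relatives of the Cyp2d cluster and its regulators Hnf4a, Nr0b2 and Klf9 were.

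Pregnancy at day 21 was compared with the pre-pregnancy liver to ask which hepatic genes differ in late gestation. Cyp17a1, a steroid hydroxylase, rose 34.4-fold (log2 change 5.11 ± 0.287 SE, adjusted p = 0.000227), and Gpx3, a secreted glutathione peroxidase, rose 15.8-fold (3.98 ± 0.168, adjusted p = 9.03e-05). Of the replicative helicase genes, Mcm6 fell by 4.58 on the log2 scale (SE 0.148, 23.8-fold lower, adjusted p = 3.59e-05), with Mcm5 (log2 change -3.70 ± 0.197) and Mcm3 (-3.16 ± 0.222) lower beside it. Other Mcm3 probe sets stood at -1.095 to -2.245, and a dim one at -0.07, so the size of its fall is not settled. C9, the pore-forming complement component, was 13.7-fold lower (adjusted p = 0.000905), and 8 of 20 cholesterol biosynthesis genes fell. The endopeptidase gene Cela3b, best known from pancreatic acinar cells, rose 8.20-fold (log2 change 3.04 ± 0.165). Among the largest rises were also Tent5a (5.68-fold), the tetraspanin Cd9 (5.19-fold), the imprinted gene Peg3 (5.06-fold), Rogdi (5.03-fold) and Spon2 (4.99-fold). Spon2 stood at 2.32 on the log2 scale, and at 1.59 and 3.05 without pregnancy replicates 1 and 2. Other large falls were those of Cnmd (18.1-fold), Bmf (9.55-fold), the checkpoint kinase Chek1 and Fignl1. The pregnant levels of Chek1 (3.63 and 4.07) and Fignl1 (4.04 and 3.63) lay near the arrays' lower quartiles, close to background, so no fold is given. Those of Cnmd (5 and 4.73), Bmf (4.91 and 4.86) and Mcm6 (5.38 and 5.31) were also dim, so their folds are imprecise. All of the genes named here had both arrays of one stage on the same side of both arrays of the other.

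**Figure D1:**
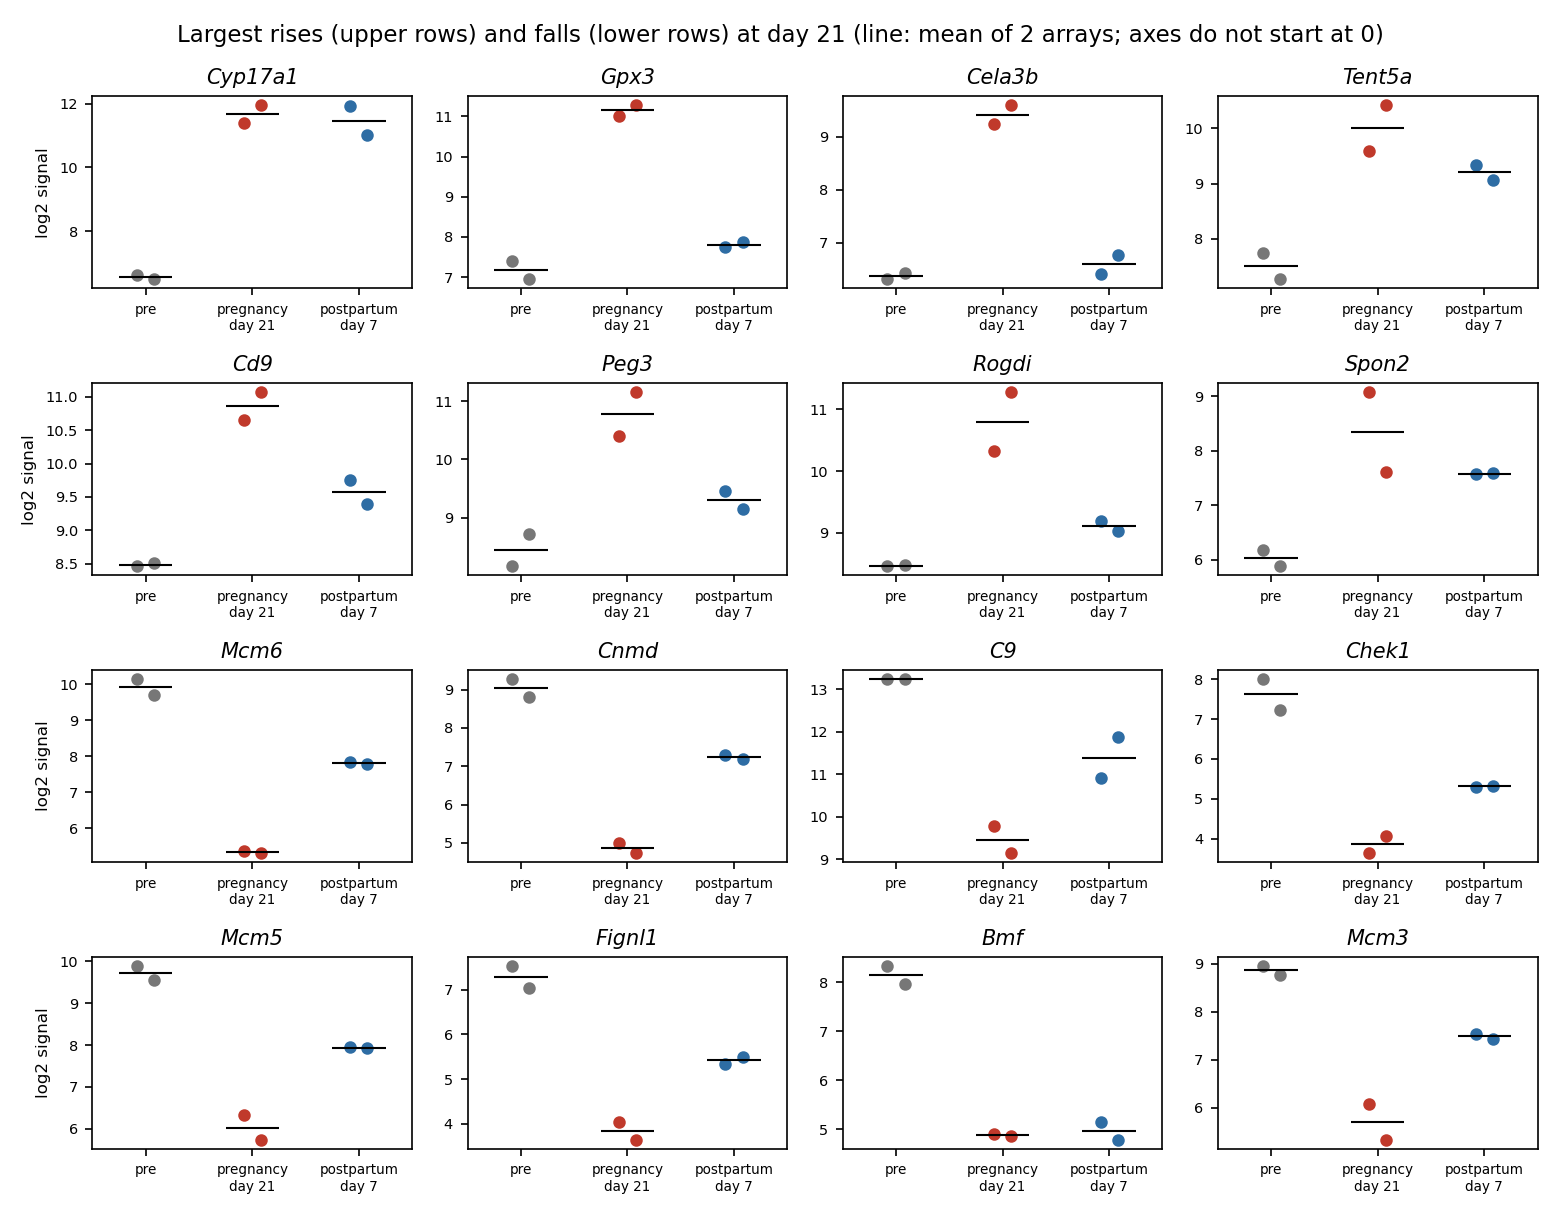
Log2 signal of the 8 genes with the largest rises and the 8 with the largest falls in pregnancy, with 1 point per array, grouped by stage, and a line at the mean of the 2 arrays; the vertical axes differ and do not start at 0. Cyp17a1 rose by 5.11 on the log2 scale in pregnancy and Mcm6 fell by 4.58.

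Of 49 measured cell cycle genes, 17 fell and 1 rose in pregnancy (18 and 1 adjusted over the list alone, camera adjusted p = 7.89e-06 and adjusted p = 0.591 with an estimated correlation). The falls included Mcm6, Mcm5, Mcm3 and Uhrf1 (pregnant arrays at 4.61 and 4.02, near background, so no fold is given), and the gene that rose was Ccne1, the G1/S cyclin (0.75 ± 0.150). Markers of other cell types moved beside them. Of 21 endothelial markers, 5 fell and 0 rose (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00286 and adjusted p = 0.534 with an estimated correlation), among them Emcn (-0.70 ± 0.173), Bmp2 (-0.65 ± 0.138) and the angiopoietin receptor Tek (-0.62 ± 0.133). Of 19 Kupffer cell and macrophage markers, 4 fell, including Timd4 (-0.91 ± 0.1002) and Lyz2 (-0.47 ± 0.123), and 2 rose, Cd163 (0.49 ± 0.111) and Ccr2 (0.46 ± 0.0986). That list was called lower (5 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.0411 and adjusted p = 0.654 with an estimated correlation), but not without pre-pregnancy replicate 2 (adjusted p = 0.142) or pregnancy replicate 2 (0.302). Of 15 neutrophil markers, 2 rose, S100a9 (0.74 ± 0.102) and Mpo (0.47 ± 0.104, near background at each stage), and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0318 and adjusted p = 0.534 with an estimated correlation). The neutrophil call was lost without pregnancy replicate 1 (adjusted p = 0.0943).

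**Figure D2:**
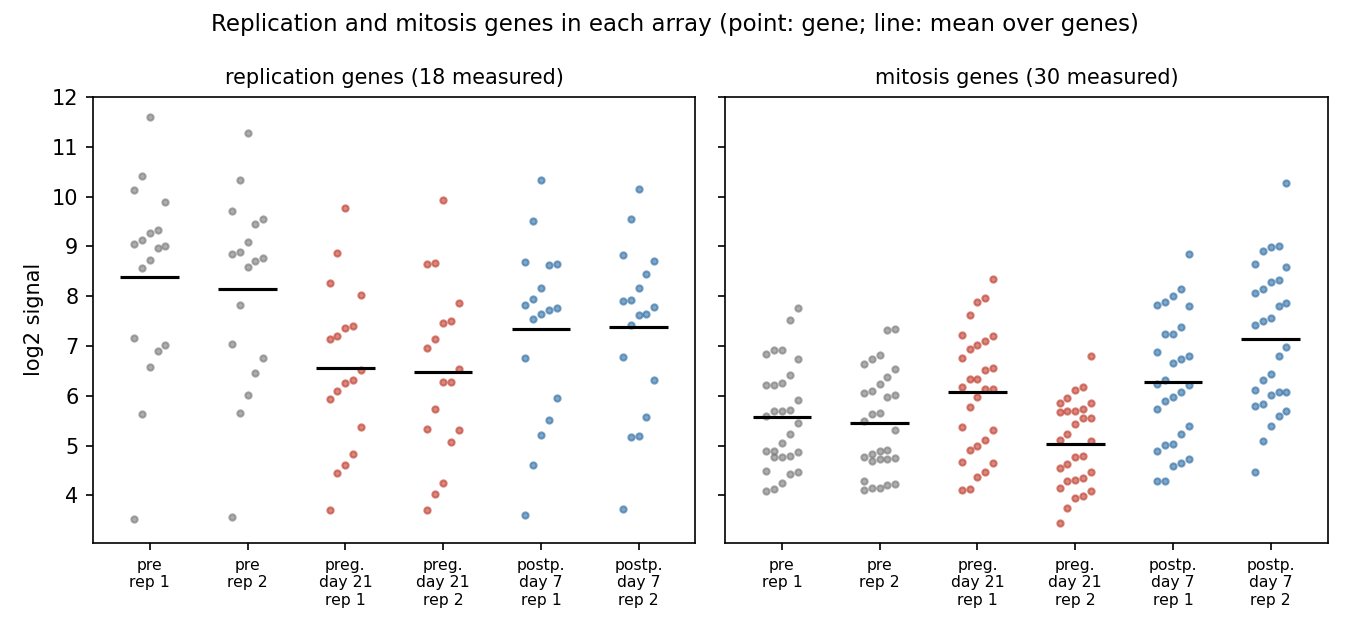
Log2 signal of the replication genes and the mitosis genes among the cell cycle list on each array, with 1 point per gene and a line at the mean over genes, a split made after the data were seen. Replication genes averaged 8.38 and 8.14 before pregnancy and 6.56 and 6.48 in pregnancy.

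Lists of lipid synthesis genes were called lower in pregnancy. Of 20 cholesterol biosynthesis genes, 8 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 2.85e-06 and adjusted p = 0.534 with an estimated correlation), including Lss (-1.65 ± 0.320), Fdps (-1.46 ± 0.364), Idi1 (-1.31 ± 0.324) and Hsd17b7 (-1.13 ± 0.187). Without pregnancy replicate 1 the differences of Fdps and Idi1 were -0.78 and -0.76 and that of Lss -1.07. Over the 6 arrays left out in turn, Lss and Hsd17b7 kept their calls 4 times, Idi1 3 times and Fdps 2 times. Of 26 lipogenesis genes, 7 fell and 1, the desaturase gene Fads1 (0.45 ± 0.106), rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00915 and adjusted p = 0.534 with an estimated correlation). The fatty acid elongase Elovl6 fell 4.21-fold (-2.08 ± 0.412), Me1 2.38-fold, Acss2 2.02-fold and the regulator Srebf1 1.88-fold. Srebf1 was at -0.91 on the log2 scale, and at -0.57 without pregnancy replicate 1. The lipogenesis call was lost without pregnancy replicate 1 (adjusted p = 0.0595). Lipoprotein and lipase genes went the other way: of 24 measured, 8 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0136 and adjusted p = 0.534 with an estimated correlation). Cd36, a fatty acid translocase, rose 4.48-fold (2.17 ± 0.236), Apoc2 3.48-fold and Lpl 2.12-fold, whereas the endothelial lipase gene Lipg fell 4.61-fold (-2.21 ± 0.115). The pregnant levels of Lipg (4.99 and 5.17) were dim, so its fold is imprecise.

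Of 21 genes for bile acid, bilirubin and sterol transport, 8 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.000877 and adjusted p = 0.534 with an estimated correlation). The basolateral efflux pump Abcc3 fell 5.15-fold (-2.37 ± 0.210), Abcb1a 1.77-fold, and the prostaglandin transporter Slco2a1 rose 1.83-fold. The bile acid uptake carrier Slc10a2 fell to near background, at 4.18 and 4.31, so no fold is given. Of 26 male-biased liver genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000115 and adjusted p = 0.534 with an estimated correlation). Hsd3b5 (-2.66 ± 0.534), Cyp2d9 (-2.16 ± 0.168), Ugt2b38 (-2.13 ± 0.351) and the complement gene C8b (-1.91 ± 0.196) fell, and Gstp1 rose (0.88 ± 0.0999). Of 28 drug-metabolising P450s, 7 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0364 and adjusted p = 0.534 with an estimated correlation); Cyp2b13 fell 3.32-fold and Cyp2c54 2.06-fold, and Cyp3a16 rose 4.69-fold and Cyp3a44 1.97-fold. The P450 call was lost without pre-pregnancy replicate 2 (adjusted p = 0.106) or pregnancy replicate 1 (0.162). Of 38 conjugation enzymes, 10 fell, including Sult1d1 (2.28-fold) and Ugt3a1 (1.94-fold), and 4 rose, all glutathione transferases: Gstm3 (2.35-fold), Gstt3, Gstp1 and Gstm2. That list was called lower (13 and 5 adjusted over the list alone, camera adjusted p = 0.0364 and adjusted p = 0.591 with an estimated correlation), but not without pre-pregnancy replicate 1 (adjusted p = 0.116) or pregnancy replicate 2 (0.118).

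The acute phase list was called higher in pregnancy and the interferon response list lower. Of 29 acute phase genes, 9 rose and 3 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.0136 and adjusted p = 0.534 with an estimated correlation), and the call was lost without pregnancy replicate 1 (adjusted p = 0.208). Saa3 rose 3.45-fold (1.79 ± 0.245), the lipopolysaccharide-binding protein gene Lbp 3.13-fold and the metallothionein Mt1 2.17-fold; Orm3 (-1.33 ± 0.197), Orm2 (-0.76 ± 0.203) and Steap4 (-0.62 ± 0.114) fell. Orm2 stood at -0.46 without pregnancy replicate 2. Of 32 interferon response genes, 11 fell and 1 rose (14 and 2 adjusted over the list alone, camera adjusted p = 0.000219 and adjusted p = 0.534 with an estimated correlation). Igtp fell 2.65-fold (-1.41 ± 0.192), Zbp1 2.30-fold and Gbp2 2.17-fold, and the related GTPase gene Gbp6 rose 1.93-fold. Gbp2 was at -1.12, and at -0.67 without pregnancy replicate 2, where it was not called (adjusted p = 0.0523). Of 35 amino acid and urea metabolism genes, 6 fell, including Prodh (-1.49 ± 0.148), Oat (-1.42 ± 0.129) and Ddc (-0.93 ± 0.159), and 3 rose, Cbs (1.22 ± 0.177), Agxt and Bhmt. That list was called lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.0253 and adjusted p = 0.534 with an estimated correlation), but not without pre-pregnancy replicate 2 (adjusted p = 0.166) or pregnancy replicate 1 (0.0595). Of 24 circadian clock genes, 5 fell, including Nampt (-1.69 ± 0.166), Lonrf3 (-1.59 ± 0.161) and Cry1 (-1.45 ± 0.194), and 1, the clock repressor Nr1d1, rose (1.43 ± 0.251). The clock list was called lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0318 and adjusted p = 0.534 with an estimated correlation), with the call lost without either pre-pregnancy array (adjusted p = 0.0632 and 0.106) or pregnancy replicate 1 (0.0595). The 2 pregnant arrays differed over the clock genes by a median of 0.425. Collection times are not given, so stage and time of day cannot be told apart for these genes.

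Klf9, a Krüppel-like factor studied as a regulator of the transgene, rose 1.82-fold in pregnancy (log2 change 0.87 ± 0.129, adjusted p = 0.00716). Its call was lost without pre-pregnancy replicate 1, where the pregnant arrays (13.01 and 12.78) still lay above pre-pregnancy replicate 2 (12.1). These values are from its brightest probe set. Other probe sets of Klf9 rose by 0.355 to 1.15, so the size of its rise is not settled. Hnf4a, the main hepatocyte nuclear receptor, was 0.11 ± 0.105 apart (adjusted p = 0.534). Nr0b2, a nuclear receptor that represses others, differed by -0.75 ± 0.586 (adjusted p = 0.425), and its pregnant arrays stood apart at 10.18 and 8.17. Its difference was -1.75 without pregnancy replicate 1 (adjusted p = 0.0360) and 0.26 without pregnancy replicate 2 (0.714), so its direction was not settled. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had pregnant arrays at 9.45 and 12.39 against 11.18 and 11.36 before pregnancy, a difference of -0.35 ± 0.758 (adjusted p = 0.786). Without pregnancy replicate 1 the Cyp7a1 difference was 1.12 (adjusted p = 0.0161) and without pregnancy replicate 2 it was -1.82 (0.00520). In the Cyp2d cluster, 2 of 8 genes fell and 0 rose (2 and 2 adjusted over the list alone, camera adjusted p = 0.362 and adjusted p = 0.591 with an estimated correlation). Cyp2d9 fell 4.47-fold (adjusted p = 0.000735) and Cyp2d13 by 1.05 on the log2 scale (SE 0.1004). Cyp2d10 (-0.04 ± 0.0987) and Cyp2d22 (-0.02 ± 0.0984, -0.07 to 0.03 over the arrays left out) were not called. Cyp2d26 (0.32 ± 0.1002, adjusted p = 0.0729) and Cyp2d40 (0.58 ± 0.168, adjusted p = 0.0586) were not called either, though both were with a trended, robust variance (0.0137 and 0.0436). Cyp2d26 was also called with the mean of all probe sets of a gene (0.0477). It has a single probe set, so its own values were the same there. Cyp2d40 was also called without pregnancy replicate 1 or either postpartum array. Cyp3a11, the main pregnane-inducible P450, fell 1.58-fold (-0.66 ± 0.105, adjusted p = 0.00885), a call lost without either pre-pregnancy array (0.0671 and 0.0577). Cyp1a2 (0.31 ± 0.121, adjusted p = 0.133, 0.16 to 0.45 over the arrays left out) and Cyp2b10 (0.21 ± 0.194, adjusted p = 0.5004, -0.04 to 0.46) were not called.

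**Figure D3:**
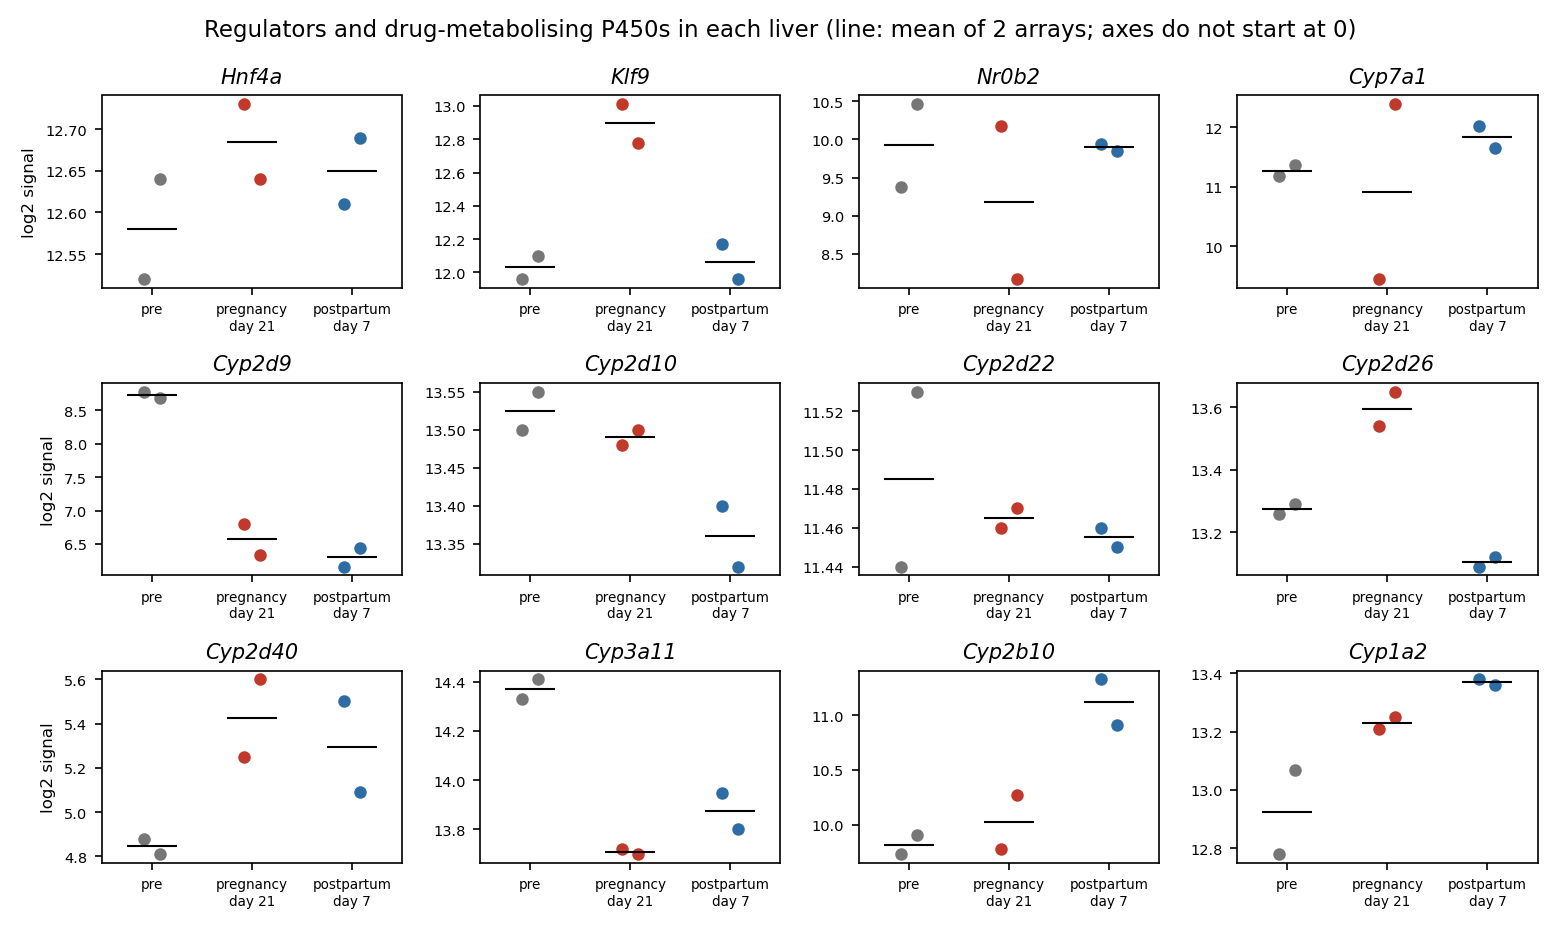
Log2 signal of 12 regulators and P450 genes on each array, grouped by stage, with a line at the mean of the 2 arrays; the vertical axes differ and do not start at 0. Klf9 was higher on both pregnant arrays, whereas the pregnant arrays of Nr0b2 lay at 10.18 and 8.17.

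In all, 2494 of 18194 genes passed limma's test in pregnancy, 993 higher and 1501 lower, 429 of them by at least 2-fold. With arrays centred on their medians 1197 were higher and 1396 lower, and after repeated quantile normalization 1074 and 1296; 59.6% of genes had non-overlapping groups, where chance gives 33.3%. Camera called 15 of 31 lists, none of which (0) held with an estimated correlation, and 16 were not called (lowest adjusted p = 0.236). The count was 323 without pre-pregnancy replicate 1, 876 without pre-pregnancy replicate 2 and 1227 without pregnancy replicate 2, and 32, 25 and 14 of the 72 called named genes lost their call there; 8 did without pregnancy replicate 1 and 2 without either postpartum array. Repeated quantile normalization ended 6 list calls (Kupffer cell, amino acid, clock, conjugation, P450 and neutrophil), and leaving out dim genes ended 7 (Kupffer cell, amino acid, clock, conjugation, P450, lipogenesis and endothelial), while camera on ranks ended the Kupffer cell, clock and conjugation calls and the mean of all probe sets the clock, conjugation and lipoprotein calls.

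**Figure D4:**
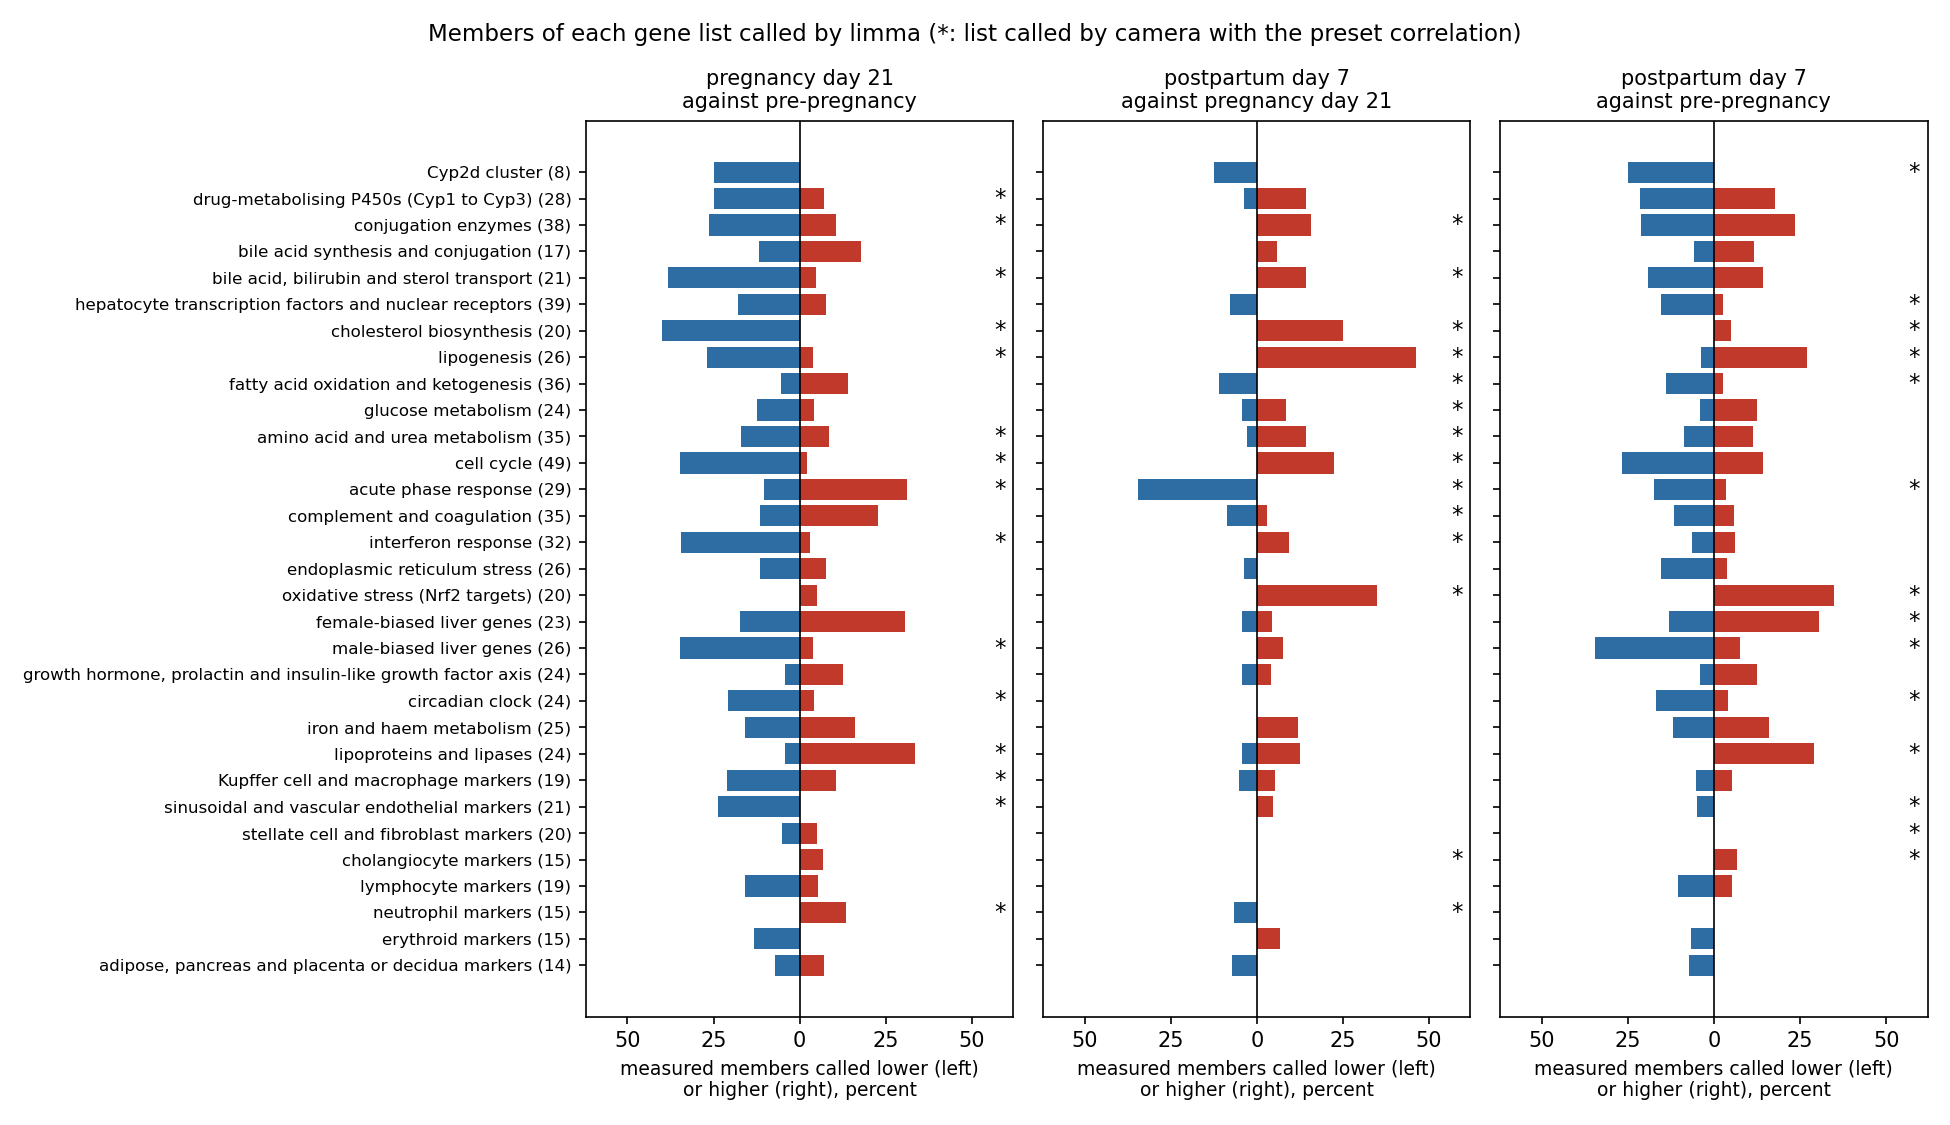
Share of each fixed list's measured genes that were called higher (right) or lower (left) in the 3 comparisons, in percent; an asterisk marks lists that camera called. In pregnancy 17 of 49 cell cycle genes fell, and postpartum 12 of 26 lipogenesis genes rose against pregnancy.

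Day 7 postpartum was compared with day 21 of pregnancy to ask what differs after birth. Elovl6 rose 7.86-fold (log2 change 2.98 ± 0.412, adjusted p = 0.0133), the acetoacetate-activating enzyme Aacs 6.57-fold (2.72 ± 0.307, adjusted p = 0.00699) and Mcm6 5.50-fold (2.46 ± 0.148, adjusted p = 0.000706). Gpx3 fell 10.2-fold (-3.35 ± 0.168, adjusted p = 0.000587), Cela3b 7.04-fold, the metallothionein Mt2 6.94-fold and the pantetheinase Vnn1 7.49-fold. Other large rises were Akr1c19 (6.73-fold), Prom1 (5.80-fold), Cnmd (5.21-fold), Serpinb1a and the cytokinesis gene Ect2. The pregnant levels of Serpinb1a (4.63 and 4.51) and that of Ect2 in replicate 2 (4.31) lay near background, so no fold is given. Those of Cnmd (5 and 4.73) and Mcm6 (5.38 and 5.31) were dim too. Ect2 stood at 2.23 on the log2 scale, and at 2.97 and 1.495 without pregnancy replicates 1 and 2, and kept its call in 2 of 6 arrays left out. Saa3 (3.61-fold), the basement membrane gene Nid1 (3.51-fold), Angptl4 (3.36-fold) and Adamts16 (3.36-fold) fell.

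Of 49 cell cycle genes, 11 rose postpartum and 0 fell (35 and 0 adjusted over the list alone, camera adjusted p = 1.51e-17 and adjusted p = 0.315 with an estimated correlation), including the proliferation marker Mki67 (2.00 ± 0.316), Mcm6, Mcm5 (1.91 ± 0.197) and Mcm3 (1.78 ± 0.222). Other Mcm3 probe sets stood at 0.25 to 0.76, and a dim one at -0.1, so the size of its rise is not settled. Of 26 lipogenesis genes, 12 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 9.86e-09 and adjusted p = 0.278 with an estimated correlation). The fatty acid synthase Fasn rose 4.29-fold, Acss2 3.97-fold and Me1 3.25-fold beside Elovl6. Of 20 cholesterol biosynthesis genes, 5 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 1.18e-14 and adjusted p = 0.315 with an estimated correlation): Lss (1.75 ± 0.320), Pmvk (1.59 ± 0.149), Dhcr7 (1.37 ± 0.181), Insig1 (1.28 ± 0.230) and Sc5d. Lss stood at 1.16 without pregnancy replicate 1, and kept its call in 2 of 6 arrays left out. Of 36 fatty acid oxidation and ketogenesis genes, 4 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 8.32e-06 and adjusted p = 0.499 with an estimated correlation), and the call was lost without pregnancy replicate 1 (adjusted p = 0.0709). They were Vnn1, Angptl4, the hormone gene Fgf21 (3.33-fold) and the transcription factor gene Creb3l3 (1.63-fold), none of which encodes an enzyme of the oxidation pathway itself. Of 24 glucose metabolism genes, Khk (1.85-fold) and Ppp1r3b (1.83-fold) rose and the glycogen synthase Gys2 fell (1.69-fold), 2 and 1 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0339 and adjusted p = 0.499 with an estimated correlation). The glucose call was lost without postpartum replicate 1 (adjusted p = 0.438) or pregnancy replicate 2 (0.0933).

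Of 29 acute phase genes, 10 fell after birth and 0 rose (15 and 1 adjusted over the list alone, camera adjusted p = 2.76e-09 and adjusted p = 0.278 with an estimated correlation), with Mt2, Saa3, Mt1 (2.48-fold) and Lbp (2.09-fold) among them. Of 15 neutrophil markers 1, S100a9, was lower (-0.53 ± 0.102) and 0 were higher, and the list was called lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.00377 and adjusted p = 0.278 with an estimated correlation). Of 35 complement and coagulation genes, 3 fell, the clotting factors F11 (-1.08 ± 0.0962) and F5 (-0.96 ± 0.111) and C8a (-0.93 ± 0.155), and C9 rose (1.93 ± 0.307). That list was called lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.000113 and adjusted p = 0.278 with an estimated correlation). Of 32 interferon response genes, 3 rose, Parp14, Dhx58 and Rtp4 (log2 changes 0.67, 0.55 and 0.54), and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 1.73e-05 and adjusted p = 0.315 with an estimated correlation). Of 15 cholangiocyte markers 0 were called in limma's test (0 also adjusted over the list alone), with Pkhd1 at 1.10 ± 0.377 and Krt19 at 1.04 ± 0.491. Krt19 stood at 0.15 without postpartum replicate 1 and at 1.92 without postpartum replicate 2. Pkhd1 stood at 1.63 and 0.57 without pregnancy replicates 1 and 2. The cholangiocyte list was called higher (camera adjusted p = 0.0261 and adjusted p = 0.499 with an estimated correlation), but not without postpartum replicate 1 (adjusted p = 0.522) or pregnancy replicate 2 (0.223).

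Of 20 Nrf2 targets of the oxidative stress response, 7 rose and 0 fell postpartum (11 and 0 adjusted over the list alone, camera adjusted p = 4.17e-06 and adjusted p = 0.278 with an estimated correlation), including Aox1 (2.48-fold), the quinone reductase Nqo1 (2.45-fold), Ephx1 (2.29-fold) and Tkt (2.07-fold). Of 38 conjugation enzymes, 6 rose, all glutathione transferases, and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 4.58e-05 and adjusted p = 0.315 with an estimated correlation); Gstm4 rose 2.77-fold and Gsta2 2.53-fold. Of 35 amino acid and urea metabolism genes, 5 rose and 1, Prodh2, fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000447 and adjusted p = 0.315 with an estimated correlation). Ddc rose 3.25-fold, Got1 2.31-fold, Prodh 2.19-fold and the urea cycle enzyme Ass1 2.08-fold. Of 21 transport genes, the efflux pumps Abcc3 (4.42-fold) and Abcc4 (2.85-fold) and the bile acid exporter subunit Slc51b (2.17-fold) rose, 3 in all, and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0455 and adjusted p = 0.499 with an estimated correlation). The transport call was lost without postpartum replicate 1 (adjusted p = 0.0909) or pregnancy replicate 2 (0.311).

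Klf9 fell 1.78-fold after birth (-0.83 ± 0.129, adjusted p = 0.0189), a call lost without either pre-pregnancy array (adjusted p = 0.0566), pregnancy replicate 1 (0.0563), postpartum replicate 1 (0.0641) or postpartum replicate 2 (0.119). Cyp2d26 fell 1.40-fold (-0.49 ± 0.1002, adjusted p = 0.0450), and no array could be left out without losing the call: the adjusted p was 0.0951 without either pre-pregnancy array, 0.0635 and 0.135 without pregnancy replicates 1 and 2, and 0.192 and 0.179 without postpartum replicates 1 and 2. Repeated quantile normalization also ended the Cyp2d26 call (0.0554). Cyp2b10, a target of the constitutive androstane receptor, rose 2.14-fold (1.10 ± 0.194, adjusted p = 0.0298). Its call was lost without either pre-pregnancy array (0.0795), pregnancy replicate 1 (0.0708), postpartum replicate 1 (0.141) or postpartum replicate 2 (0.0543). Cyp7a1 differed by 0.92 ± 0.758 (adjusted p = 0.539), by -0.56 without pregnancy replicate 1 (adjusted p = 0.158) and by 2.39 without pregnancy replicate 2 (0.00439), so its direction was not settled. Nr0b2 differed by 0.72, by 1.73 without pregnancy replicate 1 and by -0.29 without pregnancy replicate 2, and was not called (adjusted p = 0.531). The differences of Hnf4a (-0.04), Cyp2d9 (-0.27), Cyp2d10 (-0.13), Cyp2d22 (-0.01), Cyp2d40 (-0.13), Cyp3a11 (0.17) and Cyp1a2 (0.14) were not called, and those of Hnf4a and Cyp2d40 turned sign with 1 array left out.

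In all, 599 genes passed limma's test between day 7 postpartum and pregnancy, 439 higher and 160 lower, 180 of them by at least 2-fold. The share called higher was 73.3%, against 62.5% after repeated quantile normalization (292 higher, 175 lower) and 64.0% with arrays centred on their medians (390 higher, 219 lower). Camera called 14 of 31 lists, of which 0 held with an estimated correlation; 17 were not called (lowest adjusted p = 0.0549). The count was 203 without either pre-pregnancy array, 305 without pregnancy replicate 2, 115 without postpartum replicate 1 and 149 without postpartum replicate 2, and 19, 15, 31 and 25 of the 59 called named genes lost their call there; 11 did without pregnancy replicate 1. Repeated quantile normalization ended the transport call (adjusted p = 0.0635), as did camera on ranks (0.243) and the mean of all probe sets (0.205), and leaving out dim genes ended the transport, cholangiocyte and glucose calls.

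Genes called in pregnancy and called back after birth numbered 347: 107 rose and then fell, among them Gpx3, Cela3b, Saa3, Mt1 and Klf9, and 240 fell and then rose, among them Mcm6, Mcm5, Mcm3, Elovl6, Abcc3 and C9. Independent lists of these sizes would share 8.73 and 36.2 genes, and simulated unchanged groups sharing the 2 pregnant arrays, which hold no real changes, gave means of 0.10 and 0.07. Across genes, the changes into and out of pregnancy correlated at -0.563, against -0.501 in the simulation, with a covariance of -0.0672 against -0.00985 simulated. Only 2 arrays are shared, too few to split, so part of the excess may come from them. The count was 88 and 113 without pre-pregnancy replicates 1 and 2, 185 without pregnancy replicate 2, and 74 and 95 without postpartum replicates 1 and 2.

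Day 7 postpartum was also compared with the pre-pregnancy liver, to ask what still differs after birth. Cyp17a1 was still 29.8-fold higher (log2 change 4.90 ± 0.287, adjusted p = 0.000862), and the cyclin gene Ccnb2 was 8-fold (log2 change 3 ± 0.626, adjusted p = 0.0300) and the enoyl-CoA isomerase Eci3 7.06-fold higher. Bmf, a pro-apoptotic BH3-only gene, was 9.03-fold lower (-3.18 ± 0.165, adjusted p = 0.000862), Cyp2b13 7.14-fold and Cyp2d9 5.39-fold lower. The postpartum levels of Bmf (5.15 and 4.78) and the pre-pregnancy levels of Ccnb2 (4.77 and 4.77) were dim, so their folds are imprecise. The junction gene Tjp3 and the proline synthesis gene Aldh18a1 rose 5.19-fold each, and Serpina4-ps1 (7.62-fold) and Nrep (5.01-fold) fell. The pre-pregnancy levels of Tjp3 (5.36 and 5.42) were dim, so its fold is imprecise. The Aldh18a1 value is that of its brightest probe set (2.375 on the log2 scale), with pre-pregnancy arrays at 5.12 and 4.77. Its other probe sets stood at 0.29 to 1.15, so the size of its rise is not settled. Serpina4-ps1 stood at -2.93 on the log2 scale, and at -2.19 and -3.67 without postpartum replicates 1 and 2.

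Of 20 Nrf2 targets, 7 were higher and 0 lower than before pregnancy (11 and 0 adjusted over the list alone, camera adjusted p = 1.71e-05 and adjusted p = 0.453 with an estimated correlation), including Pgd (2.66-fold), Aox1 (2.17-fold), Nqo1 (1.95-fold) and Srxn1 (1.85-fold). Another of the 7, Keap1, encodes the repressor of Nrf2. Srxn1 stood at 0.89 on the log2 scale and its other probe sets at 0.035 to 0.415, so the size of its rise is not settled. Of 26 lipogenesis genes, 7 were higher and 1, the phosphatidate phosphatase Lpin1 (-1.09 ± 0.238, or -0.72 and uncalled without postpartum replicate 2, adjusted p = 0.138), lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00105 and adjusted p = 0.453 with an estimated correlation); Acacb was 2.51-fold, Fasn 2.27-fold and Acss2 1.97-fold higher. Of 20 cholesterol biosynthesis genes, Tm7sf2 was called higher (0.44 ± 0.0973), 1 gene, and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0207 and adjusted p = 0.793 with an estimated correlation). The cholesterol call was lost without pre-pregnancy replicate 2 (adjusted p = 0.0711) or postpartum replicate 1 (0.295). Of 24 lipoprotein and lipase genes, 7 were higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00794 and adjusted p = 0.453 with an estimated correlation), including Cd36 (3.01-fold), Pltp (2.69-fold), Lpl (2.35-fold) and Vldlr (2.22-fold). With the mean of all probe sets of a gene the lipoprotein call was lost (adjusted p = 0.0570). Of 36 fatty acid oxidation and ketogenesis genes, 5 were lower, including Angptl4 (2.41-fold), the nuclear receptor Ppara (1.82-fold), Cpt1a (1.66-fold) and Cyp4a12a (postpartum level below the array's lower quartile, so no fold is given), and 1, Acads, was higher (0.72 ± 0.108). That list was called lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0112 and adjusted p = 0.793 with an estimated correlation).

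Of 26 male-biased genes, 9 were lower postpartum than before pregnancy, including Cyp2d9, Ugt2b38 (3.66-fold), C8b (3.18-fold) and Keg1 (2.49-fold), and 2, Dct (1.04 ± 0.175) and Gstp1 (0.82 ± 0.0999), were higher (10 and 3 adjusted over the list alone, camera adjusted p = 0.00445 and adjusted p = 0.453 with an estimated correlation). The postpartum levels of Ugt2b38 (4.77 and 5.5) were dim, so its fold is imprecise. Of 23 female-biased genes, 7 were higher, including Cyp17a1, Cyp3a16 (3.13-fold) and Lpl, and 3, Cyp2b13, Slc22a26 and Fmo2, were lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.0388 and adjusted p = 0.453 with an estimated correlation). The female-biased call was lost without pre-pregnancy replicate 2 (adjusted p = 0.129) or postpartum replicate 1 (0.0870). Of 8 Cyp2d genes, Cyp2d9 and Cyp2d13 (1.86-fold) were lower, 2 in all, and 0 higher (2 and 0 adjusted over the list alone, camera adjusted p = 0.0207 and adjusted p = 0.453 with an estimated correlation), with Cyp2d40 at 0.45 ± 0.168 (0.25 to 0.66 over the arrays left out) and Cyp2d26 at -0.17 ± 0.1002. Without pre-pregnancy replicate 2 or postpartum replicate 1 the Cyp2d call was lost (adjusted p = 0.0613 and 0.0531). Of 39 hepatocyte transcription factors, 6 were lower, including Esr1 (2.26-fold), Cebpb (1.95-fold), Ppara and the glucocorticoid receptor Nr3c1 (1.74-fold), and 1, Cebpa, was higher (0.54 ± 0.109). That list was called lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.0112 and adjusted p = 0.453 with an estimated correlation).

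Of 24 clock genes, 4 were lower postpartum than before pregnancy, Nampt (3.07-fold), Cry1 (2.80-fold), Wee1 (2.30-fold) and Lonrf3, and Nr1d1 was 2.63-fold higher, 1 gene (7 and 1 adjusted over the list alone, camera adjusted p = 0.00875 and adjusted p = 0.453 with an estimated correlation). Without collection times, these clock differences cannot be told apart from a different time of day. Of 29 acute phase genes, 5 were lower, including Mt2 (3.36-fold), Steap4 (2.17-fold), Orm3 (1.97-fold) and Orm2 (1.79-fold), and Apcs was higher (0.69 ± 0.102), 1 gene (5 and 3 adjusted over the list alone, camera adjusted p = 0.0207 and adjusted p = 0.574 with an estimated correlation). The acute phase call was lost without pre-pregnancy replicate 2 (adjusted p = 0.0673) or postpartum replicate 1 (0.0658). Of 21 endothelial markers, Bmp2 was lower (-0.65 ± 0.138), 1 gene, and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.00875 and adjusted p = 0.574 with an estimated correlation). Of 15 cholangiocyte markers, the keratin gene Krt18 was higher (0.63 ± 0.112), 1 gene, and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0112 and adjusted p = 0.574 with an estimated correlation), a call lost without postpartum replicate 1 (adjusted p = 0.290). Krt18 was bright (means 11.34 before pregnancy and 11.97 postpartum) where Krt19 of the same list was dim (5.07 and 6.185). Its rise may thus not be particular to cholangiocytes. Of 20 stellate cell and fibroblast markers, 0 were called in limma's test (0 also adjusted over the list alone), with Lrat at -0.85 ± 0.313 and Acta2 at 0.74 ± 0.290. Acta2 stood at 0.22 without postpartum replicate 1 and at 1.26 without postpartum replicate 2. The stellate list was called lower (camera adjusted p = 0.0455 and adjusted p = 0.792 with an estimated correlation), but not without pre-pregnancy replicate 1 (adjusted p = 0.0608), pre-pregnancy replicate 2 (0.0937) or postpartum replicate 2 (0.866).

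Cyp2b10 was 2.47-fold higher postpartum than before pregnancy (1.31 ± 0.194, adjusted p = 0.0109), a call lost without pre-pregnancy replicate 1 (adjusted p = 0.125), pre-pregnancy replicate 2 (0.0606) or postpartum replicate 1 (0.0506). Cyp3a11 was 1.41-fold lower (-0.50 ± 0.105, adjusted p = 0.0315), a call lost without pre-pregnancy replicates 1 and 2 (0.160 and 0.140) and without postpartum replicates 1 and 2 (0.0715 and 0.193). Klf9 differed by 0.04 ± 0.129 (adjusted p = 0.922), Hnf4a by 0.07, Nr0b2 by -0.03, Cyp7a1 by 0.57 ± 0.758, Cyp2d10 by -0.17 and Cyp2d22 by -0.03, with no call. Klf9, Nr0b2 and Cyp2d22 turned sign with 1 array left out. Other Klf9 probe sets differed by -0.56 to 0.13, so a full return of Klf9 is not settled. Cyp1a2 differed by 0.45 ± 0.121 (adjusted p = 0.0674) and was called with a trended, robust variance (0.0161).

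In all, 1393 genes differed between day 7 postpartum and pre-pregnancy in limma's test, 711 higher and 682 lower, 262 of them by at least 2-fold. The balance turned under other settings: 641 higher and 789 lower after repeated quantile normalization, 697 and 810 with arrays centred, 727 and 841 with the replicate number as a block, and 582 and 700 with the mean of all probe sets. Of the genes that rose in pregnancy, 323 were still higher, and of those that fell, 503 were still lower; independent lists would share 38.8 and 56.3, and the simulation gave 0.05 and 0.06. These 2 comparisons share the pre-pregnancy arrays, which are too few to split, so part of the excess may come from them; their changes correlated across genes at 0.653 (0.5004 simulated), with a covariance of 0.0850 (0.00983 simulated). At day 7 postpartum 131 genes were higher than at both other stages and 32 were lower; Gstm3 is among both the 131 and the 323. Independent lists would share 17.2 and 6.00, and the simulation gave means of 0.09 and 0.09 with maxima of 3 and 1. Those comparisons share the postpartum arrays, so part of that excess may come from them. Camera called 14 of 31 lists, of which 0 held with an estimated correlation; 17 were not called (lowest adjusted p = 0.0967). The count was 73 and 331 without pre-pregnancy replicates 1 and 2 and 537 and 260 without postpartum replicates 1 and 2, and 39, 26, 18 and 21 of the 47 called named genes lost their call there. Repeated quantile normalization ended the acute phase and stellate calls, leaving out dim genes ended 8 (acute phase, cholangiocyte, cholesterol, fatty acid oxidation, female-biased, transcription factor, endothelial and stellate), camera on ranks ended the Cyp2d and female-biased calls, and the mean of all probe sets the female-biased and lipoprotein calls.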

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

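All alternatives were planned. The count in pregnancy against pre-pregnancy (2494) was 4696 with every probe set by itself, 429 with a 2-fold change and 4066 at the looser threshold; postpartum against pregnancy (599) it was 976, 180 and 1337; postpartum against pre-pregnancy (1393) it was 2722, 262 and 2489; and for genes that changed and changed back (347) it was 551, 87 and 775. Probe sets by themselves test more features, and the 2-fold and looser thresholds move the bar by construction. Fitting only the 2 groups compared gave 1977, 203 and 1582 in the 3 comparisons. The differences are the same there, and only the estimate of the spread changes. Leaving out either array of the third group gives the same counts, as a group of 1 array adds nothing to that estimate. Calls lost that way, such as those of Klf9, Cyp2d26 and Cyp2b10 postpartum against pregnancy without either pre-pregnancy array, reflect the spread and not a changed difference. The balance of the 1393 genes, 711 higher and 682 lower, turned to 641 and 789 after repeated quantile normalization. Leaving out 1 array gave 323 to 1977, 115 to 528, 73 to 1582 and 74 to 364, with the lowest counts without pre-pregnancy replicate 1 (323 and 73) and postpartum replicate 1 (115 and 74); the cause was not tested. Of the 2494, 599 and 1393 genes, 2071, 419 and 1302 were also called after repeated quantile normalization, with 0 of opposite sign; with the mean of all probe sets 12, 1 and 11 had the opposite sign. Nothing in the labels says that equal replicate numbers pair the livers. Replicate differences correlated at 0.0285, 0.111 and -0.0273 between stages, which shows no strong pairing and cannot exclude a weak one. With the replicate number as a block the counts were 2612, 574, 1568 and 340, and 0, 3 and 1 of the called named genes lost their call, Cyp2d26 among them (adjusted p = 0.0551); of the lists the female-biased call postpartum against pre-pregnancy was lost (0.0537).

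With the correlation estimated per list, camera called 0 lists in any comparison (lowest adjusted p = 0.534, 0.278 and 0.453). Direction turned and was then called in 2 results; other uncalled genes and lists changed sign without a call, Cyp7a1 postpartum against pregnancy (0.92) to -0.56 without pregnancy replicate 1 among them. The endoplasmic reticulum stress list, uncalled postpartum against pregnancy (adjusted p = 0.962), was called higher without pregnancy replicate 2, with a range of 0.00930 to 0.960 over the arrays left out. Cyp7a1 in pregnancy, uncalled at -0.35, was 1.12 without pregnancy replicate 1 and -1.82 without pregnancy replicate 2, the range over the arrays left out; its 2 pregnant arrays lie on either side of the pre-pregnancy ones. The cause was not tested. Signal near background limits the changes measured: the pregnant levels of Chek1, Fignl1, Uhrf1, Slc10a2 and Serpinb1a lie near the arrays' lower quartiles. The postpartum level of Cyp4a12a lies below them.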

Other observations

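The gene families, the test of Cela3b's single probe sets and both tests of the replication pattern were chosen after the result was seen. The replication tests were first run over all members, where both explanations were argued against (median 0.015 over 30 mitosis genes). They were then redone on bright members in each pregnant liver, because many mitosis genes lie near background and the 2 pregnant livers disagreed, and the bound for the immune markers was made stricter. This left a smaller share of dividing cells open, and the immune markers still lay above their bound. The test of bile acid receptor targets was first read as arguing against its explanation, since its median lay under the bound, and was read as open once its spread was counted, after the value was seen. The check on picking among 12 genes was also added after the result was seen, and the pool its random genes are ranked in was corrected once. Gene families were formed from symbol stems with at least 8 members, 315 in all, and tested with camera. In pregnancy 5 families were called lower: Mcm, the replicative helicase genes (8 of 10 genes fell, adjusted p = 3.23e-10), Nup, nuclear pore proteins (7 of 19, 0.00143), Haus, spindle augmin subunits (5 of 8, 0.00791), Mrpl, mitochondrial ribosomal proteins (6 of 47, 0.0197), and Ugt, glucuronosyltransferases (5 of 11, 0.0296). Nup160 fell by 1.69 (SE 0.136), Haus6 by 1.56 (0.211) and Mrpl18 by 0.93 (0.121). With an estimated correlation 0 of these calls held (adjusted p = 0.848 for each). The medians of all 5 stayed below 0 under both other scalings, that of Mrpl at -0.16, and at -0.08 after repeated quantile normalization.

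After birth 10 families were called against pregnancy. Mcm (5 of 10 genes rose, adjusted p = 2.99e-06), Mrps (2 of 29, 0.000350), Mrpl (2 of 47, 0.00661), Nup (1 of 19, 0.00777), Ints (1 of 15, 0.00777), Parp (2 of 11, 0.0172) and Polr (1 of 25, 0.0368) were higher, as were Haus and Anapc with 0 members called (0.0308 and 0.0313). Serpina, a family of secreted protease inhibitors, was lower (3 of 14, 0.0172). With an estimated correlation 0 of the calls held (lowest adjusted p = 0.755), and after repeated quantile normalization the medians of 6 shrank by over 1.5 times: Polr (0.14 to 0.02), Mrpl (0.17 to 0.08), Parp (0.23 to 0.11), Anapc (0.19 to 0.10), Nup (0.26 to 0.14) and Mrps (0.21 to 0.13). None of the 10 changed sign. Against pre-pregnancy, Mcm alone was called (8 of 10 lower, adjusted p = 2.76e-08; 0.998 with an estimated correlation).

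Cela3b rose in both pregnant livers and fell back after birth. Pancreatic tissue carried over at dissection would bring the other acinar transcripts, but the median change of 20 measured acinar genes was 0.215 ± 0.107, with 2 called higher, Pnliprp1 and Pnliprp2, and 1 called lower, Cela1, at -1.18, while Prss2 stood at 0.14; 4 of the 20 are in a list used above and 1 is bright in the pre-pregnancy liver. A single misreading probe set is argued against by the smallest change over its 4 probe sets, 3.04, with the largest at 5.48. Expression by liver cells in late pregnancy may be the source, a hypothesis that was not tested, and probe sets that cross-read a related transcript stay open.

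Nr0b2 and Cyp7a1 stood apart between the 2 pregnant livers, by 2.01 and -2.94. The Nr0b2 difference lay at the 99.9 percentile of 1767 genes of like brightness, past a bound of 99, and that of Cyp7a1 at 99.9. The bound was set before the ranking, but the genes were taken up because their pregnant arrays stood apart. This ranking alone thus cannot decide whether overall spread between these arrays is the source. Nr0b2 and Cyp7a1 were picked among 12 genes named before the data were seen. Of 10000 random sets of 12 genes of like brightness, a share of 0.0390 held as high a rank and 0.0094 as many past 99. The first share makes picking less likely by a narrow margin. Nr0b2 and Cyp7a1 may move together, unlike randomly drawn genes, so the second may be too low. Picking is thus not excluded. Livers taken at different clock times may be a source. The 24 clock genes differed in size by a median of 0.425, at the 100 percentile of 10000 random lists of like brightness (highest 0.315). The postpartum pair was also at 100 (0.280) and the pre-pregnancy pair at 88.4, so that size is not particular to the pregnant pair. Directions were not tested. Pregnancy replicate 1 was higher in Arntl (1.96), Nfil3 (0.78) and Clock (0.68). It was lower in Usp2 (-2.58), Dbp (-1.5), Per2 (-1.24) and Per3 (-1.21), whereas Bhlhe40 (0) and Hlf (-0.07) hardly differed. A different bile acid receptor signal and no such difference cannot be told apart, as 8 induced targets had a median of 0.17 ± 0.112, too near the bound for their spread; collection times and feeding are not given in the sources used here.

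Replication genes were lower in pregnancy (16 of 18 fell, median -1.60) while 0 of 30 mitosis genes were called; all 18 and all 30 are also members of the cell cycle list. A smaller share of dividing cells cannot be told apart from a change within cells: the 10 bright mitosis genes had a median of -0.0325 ± 0.210, but 0.71 in 1 pregnant liver and -0.92 in the other, on either side of the bound of -0.80. A loss of lymphocytes or macrophages as deep as that bound is argued against. Their 19 bright markers had a median of -0.24 ± 0.142, and -0.06 and -0.38 in the 2 livers, above that bound in each. A smaller loss, or one limited to dividing cells among them, stays open, and the Kupffer cell and macrophage list was itself called lower. Postpartum, replication genes stayed below pre-pregnancy (13 of 18 lower, median -0.995) while 7 of 30 mitosis genes were higher (median 1.24).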
